A study of Mus musculus with 3 samples.

How the data were processed

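RNA sequencing libraries were made from eyes of rhodopsin knockout mice on a C57BL/6 background, 4 weeks old, with pooled RNA of 4 mice in each of 3 libraries. Per the labels' protocols, poly(A) RNA was selected and reverse transcribed with random primers. The labels name the tissue as eye, and the protocol describes homogenised retinas. The protocol text used here describes no step that marks strand, so reads from overlapping genes on opposite strands may not be told apart.

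The authors deposited 1 table of RPKM values, with a row per gene symbol and a column per library. Per the submitters' processing notes, GSNAP, HTSeq and the mm9 genome build were used, with no version or role given. The annotation, the treatment of reads that match several places, the denominators of the RPKM values and any filter are not given in the sources used here. Each column was matched to its library by the number in its name, which the sample titles share. The table holds 22692 symbols and 0 rows for mitochondrially encoded genes. The summed RPKM was 376426, 409465 and 442607 in replicates 1, 2 and 3.

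All 3 libraries belong to one genotype, so no model between groups was fitted and no adjusted p-value is given. RPKM values were not treated as counts. Levels were compared as log2(RPKM + 1), a scale with a pseudocount of 1 that understates differences of genes with low values. Rho was compared with rod genes, and rod with cone genes, as a difference within each library, followed by an exact two-sided sign-flip permutation test over the 3 differences, whose smallest possible p is 0.25. The level of a gene list was its median per library, set against medians of 10000 random lists of the same size from genes with a mean of at least 1 RPKM. The spread of a list was the median over its members of the SD over libraries, set against 10000 random lists matched for mean expression in 20 bins. Lists at or above percentile 97 were called wide and at or below 3 narrow, and lists with under 4 members at a mean of at least 1 RPKM were not ranked for spread, though their level was. Genes were counted as differing between libraries when the highest value was over 2 times the lowest.

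The 29 gene lists, these tests and bounds, and the alternatives were fixed before the data were examined, except for 1 pair of alternatives that the text names as later. Of 417 different symbols in the lists, 416 were found, 6 list entries under an older or other name, and Hbb-bt was not found. Genes were named in the text by rule. The rule took Rho, the 15 genes with the highest mean, the 4 highest members and the lowest member of each list, the 10 genes with the largest SD among those with a mean of at least 5 RPKM, and all members of the sex-linked and photoreceptor transcription factor lists. Not every gene the rule allows is printed. Genes outside it are said to have been chosen after their values were seen, apart from list members whose only use is in a count.

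Depth was estimated from the values. In 2998 to 3021 genes with low values per pair of libraries, the most frequent ratio between libraries gave the ratio of depths, which was 0.913 for replicate 2 and 1.08 for replicate 3 relative to replicate 1. Lengths of 26 genes with a single transcript in the GENCODE M21 annotation gave approximate reads per kilobase at 1 RPKM of 47.1, 43.0 and 50.9, from the 14 genes that shared one step. For a 1 kilobase gene at 1 RPKM, counting error alone then has an SD of 0.21, 0.22 and 0.20 on the log2 scale. Among 12064 to 12067 genes with over 20 estimated reads in both libraries, 39.1%, 43.9% and 32.9% differed by more than 2 counting SDs between replicates 1 and 2, 1 and 3, and 2 and 3. PCR copies are not independent molecules, so these figures cover counting error only. GENCODE M21 belongs to a different genome build than mm9, and it was used for transcript lengths, GC content and sequence windows, never for positions.

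The steps were tested on simulated libraries drawn at the estimated depths. Beyond counting error, each gene was given noise of the same size, drawn independently of other genes. For the count of genes over 2-fold, 20360 genes were simulated. The changed genes were drawn from those with a mean of at least 5 RPKM. All of the 67 genes changed 2.5-fold and of the 67 changed 4-fold were counted (100%), and none of the 66 changed 1.5-fold (0%). Of the 11947 unchanged genes with a mean of at least 1 RPKM, 0.193% were counted. Detection of changed genes between 1 and 5 RPKM was not simulated. For the wide lists, run on 12158 genes, 3.5% of 200 unchanged random lists were called wide. Lists with all 15 members changed 2.5-fold were called in 100% of 50 draws, and lists with 5 of 15 members changed in 44%. Depth ratios put into the simulation were recovered as 0.913, 1.08 and 1.18.

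Alternatives were a pseudocount of 0.1, rescaling of each library to an equal sum (the TPM scale), median-of-ratios scaling with size factors of 0.985, 1.03 and 0.987, other minimum values, the mean in place of the median of list members, and leaving out each replicate in turn. Rescaling to equal sums moved the median of all genes by -0.22 between replicates 3 and 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. No other genotype was analysed here.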

Results

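The transcriptome of the eye was measured by RNA sequencing in mice without a functional gene for rhodopsin, the light-sensing pigment of rod photoreceptors. One group was analysed here, rhodopsin knockout mice on a C57BL/6 background at 4 weeks of age, with 3 libraries (replicates 1, 2 and 3). Each library was made from pooled RNA of 4 mice, so the spread between libraries holds differences between pools together with technical noise. The labels give the tissue as eye, while the extraction protocol describes retinas. Lens genes took 24.5%, 26.1% and 34.3% of the summed RPKM of replicates 1, 2 and 3. The corneal keratin Krt12 had a mean of 2773 RPKM. These values argue against libraries of retina alone. The level of a list named after a retinal cell type may therefore come in part from other tissues. The design text speaks of more than one genotype, but other genotypes were not analysed here, so no value below is a difference between genotypes. Values are the authors' RPKM (reads per kilobase of gene, scaled to sequencing depth) for 22692 gene symbols. Genome coordinates are left out, because the build named for the data is mm9 and the annotation at hand belongs to another build. From the steps between low values, replicate 2 had 0.913 times and replicate 3 had 1.08 times the sequencing depth of replicate 1. The reads behind 1 RPKM over 1 kilobase came to roughly 47.1, 43.0 and 50.9 in replicates 1, 2 and 3, an approximate figure that rests on 14 genes with a single annotated transcript.

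Rho, the targeted gene, was not at 0 in any library. Its level was 24.5 RPKM in replicate 1, 26.2 in replicate 2 and 67.1 in replicate 3, a mean of 39.3 ± 24.1 (SD, n = 3), and its rank among all genes was 2470, 2364 and 732. At the approximate depths these values correspond to 1155, 1127 and 3413 reads per kilobase, so counting error was small beside the 2.74-fold range between libraries. Relative to Gnat1, the alpha subunit of the rod transducin that rhodopsin activates, Rho stood at 0.0974, 0.0747 and 0.0746 times the Gnat1 value. The values are for the gene as a whole and do not show which part of it the reads came from. Against the median of 16 rod phototransduction genes in the same library, Rho was 0.45 higher on the log2 scale in replicate 1, -0.29 in replicate 2 and 0.16 in replicate 3. The mean difference of 0.11 ± 0.37 (SD, n = 3) was smaller than the spread between libraries (exact two-sided sign-flip permutation test, p = 0.75, where 0.25 is the smallest p that 3 libraries allow). Its sign was not stable, since with the mean of the rod genes in place of their median the difference was -0.11.

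Rod genes were present in all 3 libraries at levels that differed widely between them. Gnat1 was at 252, 351 and 899 RPKM in replicates 1, 2 and 3. Sag, the rod arrestin, was at 137, 222 and 547 RPKM, Pde6g, a subunit of the rod phosphodiesterase, at 132, 179 and 393, and the calcium sensor Rcvrn at 87.8, 131 and 327. The lowest member was Cngb1, a subunit of the rod cyclic nucleotide channel, at 2.92 ± 1.68 RPKM (SD, n = 3). All 16 rod phototransduction genes were highest in replicate 3, also under the 2 other scalings tried, and 14 of them differed over 2-fold between libraries. Each was lowest in replicate 1 in the deposited values, and 15 were after rescaling to equal sums. The median of the list was 4.23, 5.05 and 5.93 on the log2(RPKM + 1) scale, and the median gene was higher in replicate 3 than in replicate 1 by 1.66. The lens list, whose median was also highest in replicate 3, took 24.5%, 26.1% and 34.3% of the summed RPKM of replicates 1, 2 and 3. Astrocyte and optic nerve genes and gliosis genes were also higher in replicate 3 than in replicate 1, each by a median of 0.60.

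Genes of the outer segment, the stacked membrane compartment that holds the visual pigment, were also highest in replicate 3. This held for all 17 such genes with a mean of at least 1 RPKM under each scaling, and 13 differed over 2-fold. The photoreceptor trafficking protein Unc119 was at 343 ± 102 RPKM, the guanylate cyclase activator Guca1a at 206 ± 72.7, the disc rim protein Rom1 at 193 ± 77.9, and Aipl1, a chaperone of phosphodiesterase, at 161 ± 78.7 (SD, n = 3 each). The guanylate cyclase Gucy2f was the lowest, at 0.715 ± 0.271 RPKM. The list's median over libraries was 3.51 ± 0.77 on the log2 scale.

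Among 13 photoreceptor transcription factors, 10 were highest in replicate 3, or 7 after rescaling to equal sums. Nrl, which directs the rod fate, was at 12.4, 15.4 and 43.1 RPKM in replicates 1, 2 and 3, and its target Nr2e3 at 13.8, 14.6 and 39.8. Over 2-fold differences were also found for Samd7 (2.34 ± 1.84 RPKM), Esrrb (4.67 ± 2.40) and Neurod1 (29.7 ± 12.6), with replicate 3 highest for each. Crx was at 19.1 ± 6.10 RPKM. Factors with smaller ranges included Otx2 (45.3 ± 1.70), Rax (50.3 ± 7.22), Mef2d (49.3 ± 4.49), Prdm1 (2.68 ± 0.212), Rorb (2.56 ± 0.251) and the cone factors Rxrg (5.85 ± 0.681) and Thrb (1.98 ± 0.114). The list median was 4.15 ± 0.53.

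Cone genes had a smaller range between the libraries than rod genes, with a median SD over libraries of 0.14 against 0.85 on the log2 scale. The cone transducin subunit Gnb3, which bipolar cells also use, was at 277 ± 85.6 RPKM, Pde6h at 106 ± 13.6, the short-wavelength opsin Opn1sw at 73.0 ± 14.6 and the middle-wavelength opsin Opn1mw at 63.1 ± 2.56. Cngb3, a cone channel subunit, was the lowest at 0.995 ± 0.101 RPKM. No cone gene with a mean of at least 1 RPKM differed over 2-fold. The cone list median was 5.22, 5.12 and 5.39. The median over cone genes of the difference between replicates 3 and 1 was 0.12, or -0.11 after rescaling to equal sums. That rescaling lowers most genes in replicate 3. Relative to the median of all genes the values were 0.12 and 0.11, but a change of scale hardly alters this relative measure. The rod median was below the cone median by -0.99 in replicate 1 and -0.07 in replicate 2, and above it by 0.54 in replicate 3. The mean difference was -0.18 ± 0.77 (SD, n = 3), with p = 0.75 in the exact two-sided sign-flip permutation test (smallest possible 0.25). It changed sign to 0.66 with the mean of the members and to 0.23 without replicate 1.

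**Figure D1:**
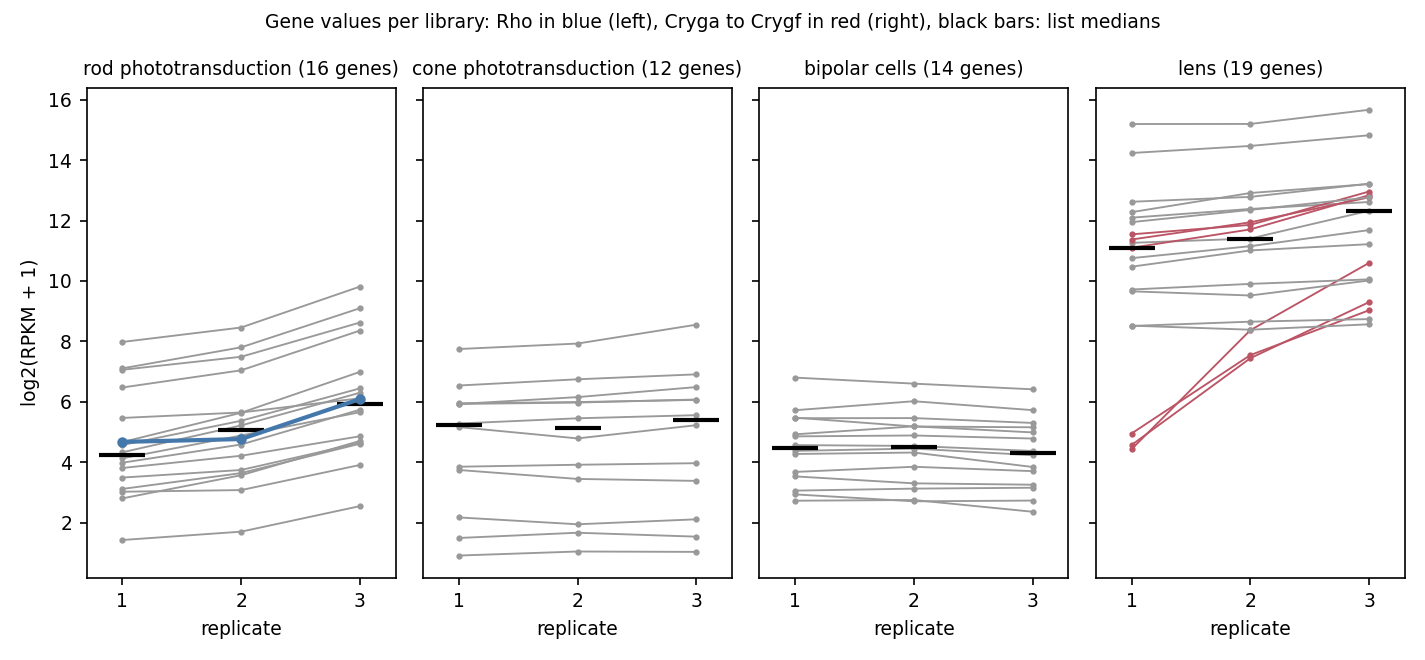
Each grey line is 1 gene of the rod, cone, bipolar or lens list, with log2(RPKM + 1) on the vertical axis and the 3 replicates on the horizontal axis, and lines join the same gene without implying an order of the replicates. Black bars are list medians, Rho is in blue and the gamma crystallins Cryga to Crygf are in red. All 16 rod and all 19 lens genes sit highest in replicate 3 (17 of the lens genes after rescaling to equal sums).

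Photoreceptor cilium genes were low, with a median of 2.28 ± 0.12. Of the 20 with a mean of at least 1 RPKM, 18 were highest in replicate 3, or 13 after rescaling to equal sums. Arl3 led them at 126 ± 20.8 RPKM, Bbs4 was at 17.3 ± 2.50 and Kif3a at 12.4 ± 0.155, and Rpgr was lowest at 0.263 ± 0.0466. Ribbon synapse genes had a median of 4.70 ± 0.17, with Snap25 at 265 ± 5.12 RPKM, the vesicular glutamate transporter Slc17a7 at 183 ± 38.7, Vamp2 at 179 ± 6.64, and Pclo lowest at 1.06 ± 0.0744.

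Lens genes were the most abundant of all lists. Crybb2, a beta crystallin, had the highest mean in the table at 42399.7 ± 8356 RPKM, followed by the alpha crystallin Cryaa at 23670.2 ± 4919, Cryba4 at 7637 ± 1701 and Cryba1 at 7378.5 ± 2264.5 (SD, n = 3 each). Of the 15 genes with the highest mean, 11 were crystallins, and the others were Apoe, Gsto1, Cst3 and the corneal keratin Krt12. All 19 lens genes were highest in replicate 3, or 17 after rescaling to equal sums, and the list median was 11.10, 11.41 and 12.33 in replicates 1, 2 and 3. The largest SDs of log2(RPKM + 1) among genes in the table with a mean of at least 5 RPKM belonged to gamma crystallins. These were Cryge, at 20.6, 329.7 and 1551 RPKM, Crygf, at 22.7, 173 and 629.7, and Cryga, at 29.9, 186 and 522. These genes have close paralogs, with 54.5%, 45.8% and 14.9% of their 36-base windows found in other genes, so the split of reads among them is uncertain.

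Genes of the cornea, sclera and eye muscle were also abundant and had a median of 8.02 ± 0.31. Krt12 was at 2773 ± 382 RPKM, Krt5 at 1949 ± 257, the corneal crystallin Aldh3a1 at 1117 ± 160 and the muscle actin Acta1 at 814 ± 258. Kera, a corneal stroma proteoglycan, was the lowest at 18.6 ± 0.958 RPKM. After rescaling to equal sums, which lowers most genes in replicate 3, 12 of 15 genes were lowest there and 2 highest. In the deposited values 9 were lowest in replicate 3, and the other 6 were highest in replicate 3. The muscle kinase Ckm was among the former at 464, 548 and 203 RPKM, and the collagen gene Col1a1 among the latter at 128, 163 and 177, both named after their values were seen. The median gene was lower in replicate 3 than in replicate 1, by -0.22 on the log2 scale. Genes of the retinal pigment epithelium, the layer that supports photoreceptors, had a median of 4.72 ± 0.17. Among them were the carrier Ttr at 744 ± 129 RPKM and the pigment genes Dct at 493 ± 37.7 and Pmel at 280 ± 22.4. Best1 was lowest at 1.01 ± 0.0617. In the retinoid cycle, which regenerates the chromophore, the median was 4.73 ± 0.15. Rgr was at 232 ± 8.71 RPKM, Rdh5 at 166 ± 3.81 and Rlbp1 at 138 ± 16.8. Rbp3 and Rdh8, which photoreceptors express, differed over 2-fold between libraries, at 174 ± 66.4 and 7.54 ± 3.98 RPKM.

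Inner retinal neurons had smaller ranges between libraries than the rods. Bipolar cell genes had a median of 4.42 ± 0.10, with the transcription factor Vsx2 at 96.9 ± 13.2 RPKM and Trpm1, the transduction channel of ON bipolar cells, at 41.4 ± 2.64. Vsx1 was lowest at 5.16 ± 0.887. Amacrine genes had a median of 3.10 ± 0.11, from Calb2 at 156 ± 10.8 RPKM to Slc17a8 at 1.35 ± 0.250. Horizontal cell genes had a median of 2.10 ± 0.10, from Sept4 at 62.7 ± 5.38 RPKM to Onecut2 at 0.174 ± 0.0353. The ganglion cell median was 4.16 ± 0.17, with the neurofilament Nefl at 133 ± 16.5 RPKM, Sncg at 123 ± 6.12 and Eomes lowest at 0.615 ± 0.0799. Between replicates 3 and 1 the median gene differed by -0.18 for bipolar, -0.24 for amacrine, -0.09 for horizontal and -0.17 for ganglion cells. These differences were negative under each scaling tried, against 1.66 for the rod list. No gene of these 4 lists with a mean of at least 1 RPKM differed over 2-fold.

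Müller glia, the main support cells of the retina, had a list median of 6.09 ± 0.07, with Apoe at 3381 ± 109 RPKM, Clu at 1933 ± 328 and Dkk3 at 443 ± 32.9. No Müller glia gene differed over 2-fold, and 10 of 15 were lowest in replicate 3. After rescaling to equal sums 13 were, but that rescaling lowers most genes in replicate 3. It left 7.66% of all genes highest there, against 25.0% before. The share of all genes lowest there was not computed. Counts of genes lowest in replicate 3, here and in other lists or sets, thus have no background share beside them. Spc25 was lowest at 4.53 ± 1.08. In the gliosis and stress list, 16 of the 19 genes with a mean of at least 1 RPKM were highest in replicate 3, or 13 after rescaling to equal sums, and the median was 3.53, 3.97 and 4.50 in replicates 1, 2 and 3. The acute-phase gene Serpina3n was at 208 ± 72.4 RPKM, and Edn2, an endothelin induced in stressed photoreceptors, at 5.83, 18.3 and 54.1. S100a6 was at 522 ± 93.5 RPKM, the metallothioneins Mt1 and Mt2 at 194 ± 16.2 and 168 ± 26.1, and Cntf was lowest at 0.0596 ± 0.0153. Astrocyte and optic nerve genes had a median of 3.70 ± 0.06, but the median gene was higher in replicate 3 than in replicate 1 by 0.60. Of 8 genes with a mean of at least 1 RPKM, 6 were highest in replicate 3, also after rescaling to equal sums. Among these were Gfap at 31.2, 37.1 and 65.6 RPKM and the myelin genes Plp1 at 24.3, 31.1 and 44.2 and Mbp at 12.3, 12.7 and 17.7, while S100b was at 57.8 ± 4.02. Pax2 was lowest at 0.407 ± 0.0350.

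Microglia and macrophage genes had a median of 4.18 ± 0.13, led by Lyz2 at 140 ± 43.2 RPKM and the complement genes C1qb at 83.7 ± 12.6 and C1qc at 56.5 ± 5.77, with Ptprc lowest at 0.357 ± 0.0462. The vascular median was 3.23 ± 0.10, with Acta2 at 148 ± 9.63 RPKM and Cldn5 at 48.6 ± 1.29, and Cspg4 lowest at 1.42 ± 0.198. Of the red blood cell genes, the beta globin listed as Beta-s was at 51.1, 250 and 61.2 RPKM and the haem synthesis gene Alas2 at 1.04, 4.00 and 1.11. Hbb-b1 and Hbb-b2 were listed at 0 in every library, as were the alpha globins Hba-a1 and Hba-a2, named here after their values were seen, so the list median was 0. Those exact zeros belong to genes with near-identical copies.

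Among genes of cellular stress, no member with a mean of at least 1 RPKM differed over 2-fold between libraries. Cell death genes had a median of 3.35 ± 0.04, with Bax at 45.3 ± 0.671 RPKM, Capn2 at 39.0 ± 2.12 and Ripk3 lowest at 0.349 ± 0.0331. The unfolded protein response, which follows misfolding in the endoplasmic reticulum, had a median of 4.63 ± 0.16, with Calr at 176 ± 18.2 RPKM, Atf4 at 83.3 ± 4.11 and Trib3 lowest at 3.53 ± 0.320. Heat shock genes had a median of 4.69 ± 0.07, from Hspb1 at 148 ± 17.6 RPKM to Hspa1a at 11.0 ± 1.27. Immediate early genes, which respond to stimulation and handling, had a median of 4.24 ± 0.14, with Junb at 54.9 ± 8.24 RPKM, Egr1 at 22.7 ± 5.89 and Npas4 lowest at 0.465 ± 0.0828. The circadian clock list had a median of 3.72 ± 0.04, with Nr1d1 at 125 ± 9.35 RPKM, Dbp at 55.1 ± 10.0 and Per2 lowest at 3.52 ± 0.102.

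Metabolic genes were high in all libraries. Glycolysis genes had a median of 6.64 ± 0.14, with the pyruvate kinase gene listed as Pkm2 at 470 ± 16.1 RPKM and Aldoa at 408 ± 47.0. Oxidative phosphorylation genes had a median of 6.83 ± 0.22, with Atp5b at 623 ± 41.7 RPKM and Cox4i1 at 621 ± 72.6, and 18 of the 19 members with a mean of at least 1 RPKM were highest in replicate 2, or 16 after rescaling to equal sums, against 44.5% and 34.3% of all genes. Cytosolic ribosomal protein genes had a median of 5.88 ± 0.10, with Rpl8 at 798 ± 43.7 RPKM and Rplp1 at 625 ± 30.3, and 17 of the 20 members with a mean of at least 1 RPKM were likewise highest in replicate 2, or 16 after rescaling. The lowest members of these lists were Eno1 at 0.167 ± 0.0729 RPKM, Cycs at 0.561 ± 0.0477 and Rpl5 at 0.385 ± 0.0556. They share 75.9%, 30.6% and 48.9% of their 36-base windows with other genes, so how their reads were assigned is uncertain. High members differ in this share as well, with 70.5% for Rplp1 and 7.82% for Rpl8.

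Sex-linked genes split the libraries. Xist, expressed from the inactive X chromosome of females, was at 0.00141, 0.00154 and 8.87 RPKM in replicates 1, 2 and 3. The Y-linked genes showed the opposite order, with Eif2s3y at 8.02 and 10.4 RPKM, Ddx3y at 5.56 and 5.88, Kdm5d at 2.27 and 2.48 and Uty at 1.07 and 1.40 in replicates 1 and 2, and each was listed at 0 in replicate 3. The labels do not give the sex of the mice. In every list, a difference between replicate 3 and both other libraries coincides with this split and cannot be told apart from it. Differences between replicates 1 and 2 lie outside it. The list median was 1.71, 1.80 and 0.

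**Figure D2:**
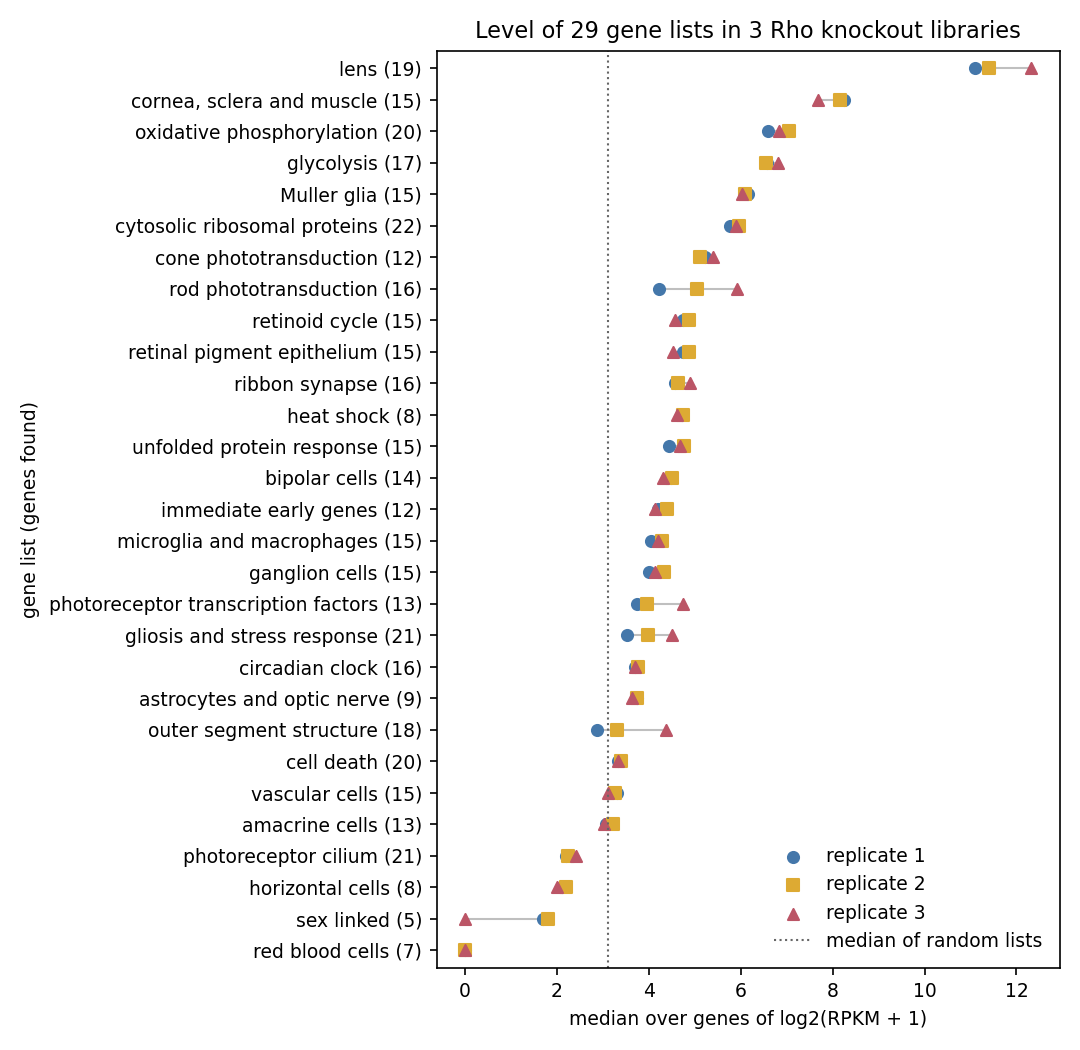
Points show the median log2(RPKM + 1) of each of 29 gene lists in replicates 1 (circles), 2 (squares) and 3 (triangles), and the dotted line is the median of random lists, near 3.12. Lens lies highest, with medians from 11.10 to 12.33, and the 3 points of the rod list spread from 4.23 to 5.93.

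Across the table, 13355 genes had a mean of at least 1 RPKM and 13027 reached 1 RPKM in every library, while 3803 were listed at 0 in all 3. Of the 29 lists, 19 had a median at or above the 97th percentile of 10000 random lists of their size, and 3 lay at or below percentile 3, namely photoreceptor cilium, red blood cells and sex linked. The place of the red blood cell list rests on its 4 globin genes listed at 0, and with 2 members at a mean of at least 1 RPKM it was not ranked for spread. The outer segment list lay at 77.0, amacrine cells at 48.6 and horizontal cells at 5.08. These percentiles describe the libraries and are not tests.

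The median gene varied by 0.10 (SD of log2(RPKM + 1) over the 3 libraries), and 280 of 13355 genes, 2.10%, differed over 2-fold between the highest and lowest library. Of the 280 genes, 154 were highest in replicate 3, although replicate 3 was highest for 25.0% of all genes in the deposited values. Without replicate 3, 45 genes differed over 2-fold, and without replicate 1, 170. The range of a gene over 2 libraries cannot exceed its range over 3, so counts below 280 follow in part from that alone. Among genes with a mean of at least 5 RPKM, the largest SDs after Cryge, Crygf and Cryga were those of Eif2s3y, Edn2 and Beta-s. Next came the rod gene Guca1b at 24.4, 48.8 and 126 RPKM and Hp at 7.12, 8.80 and 1.37. Rnf207, at 4.28, 7.64 and 20.9, and Sag followed. Correlations across genes on the log2 scale were 0.992 for replicates 1 and 2, 0.986 for 1 and 3 and 0.990 for 2 and 3 (Pearson's r, where genes are not independent replicates).

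Matched for expression, 12 of 28 lists varied more between libraries than at least 97% of random lists, and 0 lists lay at or below percentile 3. The 12 were rod phototransduction, outer segment structure, photoreceptor transcription factors, photoreceptor cilium, gliosis, lens, cornea, astrocytes and optic nerve, immediate early genes, heat shock, oxidative phosphorylation and sex linked. Random lists in simulated libraries passed this bound in 3.5% of cases, close to what the bound itself fixes. Simulated genes varied independently of each other, and members of real lists may not, so 3.5% is no chance rate for the 12 lists. Without replicate 3, 4 lists passed it, and 3 lists (rod, outer segment and lens) did so under every alternative. Heat shock passed the bound in the main form only, and lay at percentiles 73.04 to 96.97 under the alternatives. Oxidative phosphorylation fell below the bound under both other scalings, without replicate 1 and, at 27.7, without replicate 2. Rescaling to equal sums moved the median of all genes between replicates 3 and 1 by -0.22. The rod, outer segment, lens and gliosis differences then stayed positive, at 1.45, 0.92, 0.58 and 0.40. The cone difference turned from 0.12 to -0.11. Differences relative to the median of all genes hardly change with scale, so they cannot test it.

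**Figure D3:**
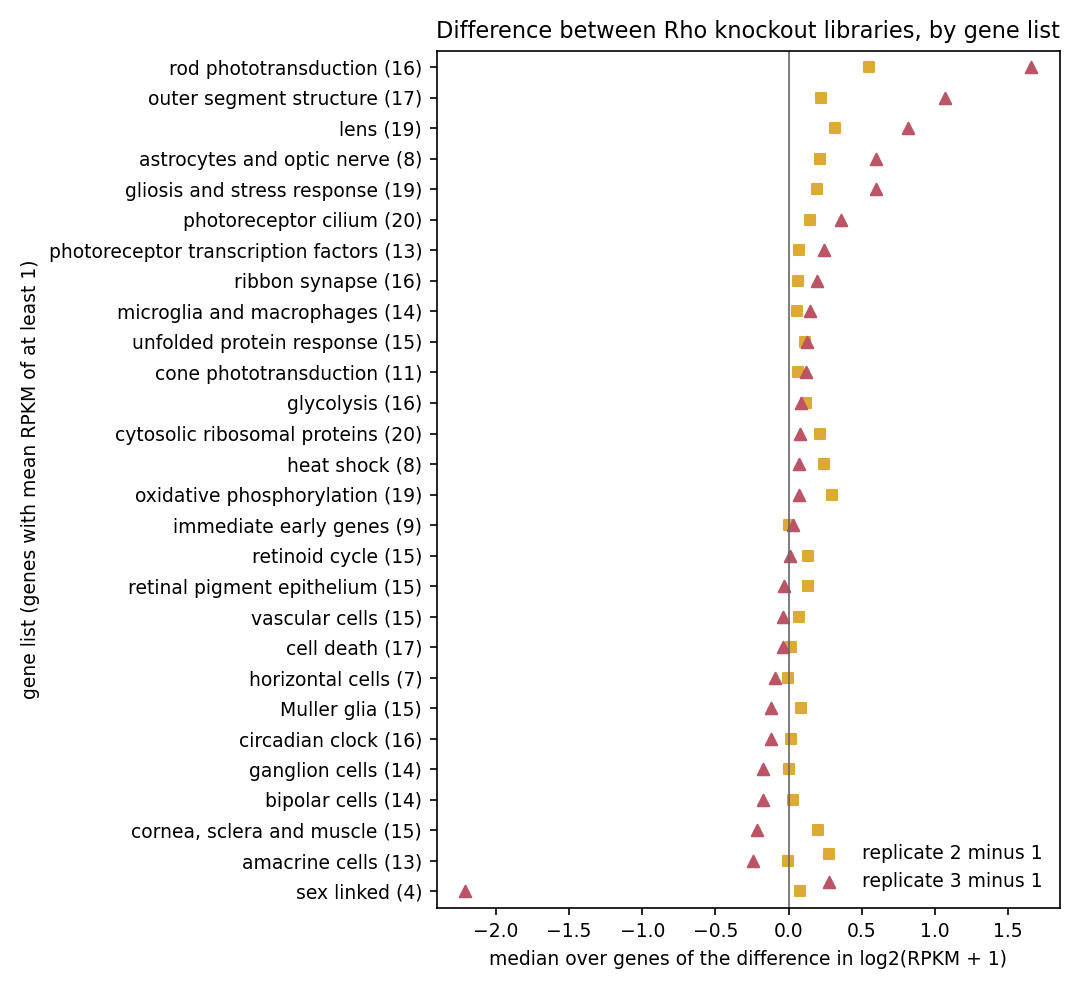
For each of 28 lists the median over its genes of the difference in log2(RPKM + 1) is shown on the horizontal axis, with squares for replicate 2 minus replicate 1 and triangles for replicate 3 minus replicate 1. The rod list lies farthest to the right for replicate 3, at 1.66, and the sex-linked list farthest to the left, at -2.21. The cone list lies near 0, at 0.12 for replicate 3, and its value is -0.11 after rescaling to equal sums.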

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

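The version of both list comparisons that kept only members specific to rods or cones was chosen after seeing the data, and all other alternatives were planned. Of 60 alternative values of the main results, 39 stayed in place under rules that allow some change. Counts had to stay within a fixed fold of the main value, and both within-library differences only had to keep their sign. The median spread had to stay within the SD of its values with each replicate left out. Rho had to stay within its SD over libraries, so 25.4 RPKM without replicate 3 passed, against 39.3 in the main form. The difference between Rho and the rod genes turned to -0.11 with the mean of members and to -0.29 with cell-type-specific members, and ranged from -0.062 (without replicate 1) to 0.30 when each replicate was left out. The difference between rod and cone genes turned to 0.66 with the mean of members and to 0.22 with cell-type-specific members, and ranged from -0.53 (without replicate 3) to 0.23 (without replicate 1). Neither difference has a stable sign, and the cause was not tested. On the TPM scale Rho was at 93.5, the median spread was 0.149 and 432 genes differed over 2-fold. More genes entered there, since 14802 reached the minimum mean of 1, against 13355 in the deposited values. The rescaling follows the summed RPKM, which differs between libraries. With a pseudocount of 0.1 the spread was 0.118, and without a filter 0.0670, because low genes then count more or sit at 0. The number of genes over 2-fold was 2867 without a filter, where more genes enter, and 127 at a minimum of 5 RPKM, where fewer do. At that minimum 9 lists had a high level, since the random lists are then higher, and 8494 genes were detected. Leaving out each replicate gave a spread of 0.0712 to 0.0893 and 45 (without replicate 3) to 195 genes over 2-fold. A gene's range over 2 libraries cannot exceed its range over 3, and a median SD over 2 tends to be lower. Values below those of all 3 libraries therefore follow at least in part from the smaller number. Wide lists numbered 4 (without replicate 3) to 13 (without replicate 1). Why the values differed with the replicate left out was not tested. Only 3 of 28 lists (rod, outer segment and lens) stayed wide throughout. Of the other values, 995 stayed in place, 201 moved, 18 passed a bound only under the alternative and 23 only in the main form. Genes near 1 RPKM are limited by depth, with a counting SD near 0.21 on the log2 scale for 1 kilobase. No paired analysis was possible because all 3 libraries belong to one group.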

Other observations

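The tests of the share of retina, of sex, of the share of lens, of the split between paralogs (both parts) and of the number of copies were chosen only after the result was seen, as were the gene sets of the next paragraph.

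Of the 280 genes that differed over 2-fold between libraries, 220 lay outside the lists, and several shared a tissue. Because these genes were picked for their variation, their agreement in direction is not evidence of its own. All 12 genes of fast muscle fibres taken this way were lowest in replicate 3, among them the troponin Tnni2 at 491, 700 and 330 RPKM in replicates 1, 2 and 3, the calcium pump Atp2a1 at 360, 478 and 193, and the myosin Myh4 at 75.0, 120 and 33.8. Further photoreceptor genes were highest in replicate 3, such as Rs1, the retinoschisin gene, at 6.70, 10.9 and 25.2 RPKM, Rtbdn at 22.3, 33.3 and 69.3, and Nxnl2 at 5.40, 8.59 and 18.9. All 10 genes of fat cells with a mean of at least 1 RPKM, out of 14 in the set, were lowest in replicate 3, and the 5 picked for their variation differed over 2-fold, with Cidec at 3.58, 3.46 and 1.05 RPKM and Adipoq at 2.91, 3.79 and 1.44. Those whose values had not been seen before the set was made included Fabp4 at 10.6, 16.5 and 8.31 RPKM, Slc2a4 at 16.8, 15.7 and 9.28 and Car3 at 79.3, 87.5 and 67.8. Symbols of microRNA, snoRNA, scaRNA or RNase P RNA genes made up 41 of the 280, with 88 such symbols at a mean of at least 1 RPKM. Among all genes the count was 280 of 13355. Genes of this kind are mostly short, so few reads lie behind 1 RPKM. How far counting error accounts for their share was not tested.

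Rod genes differed between the libraries, with the median gene of the list 1.66 higher on the log2 scale in replicate 3 than in replicate 1. A larger share of retina in replicate 3 would raise inner retinal neurons too, but 40 bipolar, amacrine and ganglion genes had a median difference of -0.19 ± 0.15 (SD over genes). GC content and transcript length do not account for it, since the difference was 1.68 after their trend was removed. The different sex of the pooled mice in replicate 3 is not the whole cause, as replicates 1 and 2, with like Xist and Y-linked values, also differed, by 0.55 and in 16 of 16 genes. Whether the pools differed in rod number or state stays open, and apart from sex no biological explanation was tested.

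The gamma crystallins Cryga to Crygf, typical of lens fibres in young eyes, differed more than the rest of the lens genes, with a median difference between replicates 3 and 1 of 2.91 ± 2.02 (SD over genes), with Crygb, Crygc and Crygd at 1.40, 1.42 and 1.74 and Cryga, Crygf and Cryge at 4.08, 4.73 and 6.17, all above the 0.59 ± 0.30 (SD over 13 genes) of other lens genes, so a larger share of lens alone does not account for them. A different split of reads between paralogs is argued against for Crygb to Crygd, which hold most of a sum that was 3.16 times as high in replicate 3, but stays open for Cryga, Cryge and Crygf, which took 0.926% of that sum in replicate 1 and 10.8% in replicate 3. A candidate explanation is younger tissue in replicate 3, although the labels give all mice the same age and no biological explanation could be tested between groups. A set of juvenile growth and cell division genes, tested as planned, was 0.22 ± 0.28 (SD over genes) higher in replicate 3 than in replicate 1 (12 of 14 genes by over 0.01, percentile 100 among matched random lists), as this explanation needs. It was also 0.28 ± 0.23 higher in replicate 2 than in replicate 1 (percentile 100), where the gamma crystallins were 1.60 higher, but between replicates 3 and 2 it differed by -0.0066 ± 0.25 (percentile 83.8) while the gamma crystallins differed by 1.31, so the explanation stays open.

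The main proteins of the ribosome are made in equal amounts. Levels of ribosomal protein genes still ranged from 0 to 798 RPKM, with 35 of 82 under 10. The 82 include paralogs such as Rpl10l, at 0 RPKM, and Rpl39l, at 0.942, to which equal amounts need not apply. The set of 73 genes used below leaves these paralogs out. Gapdh and Ppia, chosen after their values were seen, were at 5.59 ± 0.355 and 0.666 ± 0.0271 RPKM (SD, n = 3). One possible explanation is that reads matching several places were not counted, and in the test fixed beforehand Spearman's rho across genes between the share of 36-base windows found in other genes and mean RPKM was -0.17. That is above -0.2, the bound set as evidence against this explanation, but by less than the SD of 0.11 from a bootstrap over genes, which was added after the value was seen. After that result 8 further measures were tried on first-listed transcripts of 73 of the 82 genes (rho of the planned measure on the longest transcripts of these genes was -0.22), giving rho from -0.45 to -0.33, among them -0.43 for the number of other genes sharing at least 100 windows, all short of the -0.5 set as evidence for it, so the explanation stays open. Of these 73 genes, the 5 that shared at least 100 windows with no other gene had a median of 447 RPKM. The 41 that did so with 4 or more other genes had a median of 3.25 RPKM. These classes were also made after the first result. Genes with copies could be high too, as Rplp0 was at 608 RPKM with 5. Transcript length had a rho of 0.086 and is argued against.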
